A study of Mus musculus with 20 samples.

How the data were processed

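Footpad skin RNA of WT and Tabby mice at 5 stages was measured on 20 Agilent arrays, 2 biological replicates per group per the labels, with Cy3-labelled footpad RNA and a Cy5-labelled reference. Per the labels, the reference pooled RNA of mouse cell lines with RNA of embryonic stem cells, and the same wording stood on all 20 arrays. Per the file headers, the spots were read with Agilent Feature Extraction 9.5.1.1, and the mean spot signal and the local background are given as an intensity for each dye. The deposited array files also hold processed signals, an intensity after background subtraction and dye normalization, and a ratio on the log10 scale of reference over footpad. The deposited value table, with 25030 probes, gives values on the log10 scale, and the authors stated neither their direction nor their centring. Set against the log10 ratios of the array files, its values followed footpad over reference plus 1 constant per probe: the SD of the difference within a probe had a median of 3.1e-05. Of its probes, 64.4% were constant within 0.001. The scale and direction are thus settled, and for these probes the centring is a constant per probe. What was done to the values of the other probes was not tested.

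The column medians of the deposited value table (log10 scale) were 2.59 and 2.58 for the WT and 2.58 and 2.59 for the Tabby arrays of E17.5, 2.57 for all 4 arrays of P1, 2.57 and 2.58 for WT P3, 2.58 and 2.57 for Tabby P3, 2.58 and 2.59 for WT P5, 2.57 and 2.58 for Tabby P5, and 2.53 for all 4 adult arrays, in the order of the replicates. The table was used as an alternative.

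Samples were grouped by genotype and stage from the labels, and the slide, the position and the scan day were read from the file headers. Each stage was a slide, and the 5 slides were scanned on 3 days, with E17.5 and adult each on a day of its own. Arrays held 43451 spots, 42034 of them probe spots for 42006 probes with 41964 distinct sequences, and 1417 control spots. From the mean signals, both channels were corrected with normexp and an offset of 50 and the log ratio was adjusted by loess within each array (limma 3.58.1 in R 4.3.3, files read with the data.table package, version 1.17.8). Control spots and spots marked as non-uniform or population outliers had no weight in the loess. Outlier spots were set to missing and spots of 1 probe were averaged. Of the 42006 probes, 32123 had a Cy3 signal marked well above background on at least 2 of the 20 arrays, 2 were missing in a group, and 32121 were tested. Between 64.7% and 72% of probes per array were well above background in Cy3, the median Cy3 signal was 90.3 to 145, and the number of arrays limits the precision.

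Each of the 10 groups had a coefficient in 1 limma model over all 20 arrays, with 10 residual degrees of freedom, 3.52 prior degrees of freedom and a prior SD of 0.104. Contrasts were tested for Tabby minus WT at each stage and averaged over the 5 stages, for genotype by stage (F test), for WT over the stages (F test) and for WT adult minus WT E17.5. Tests were two-sided with Benjamini-Hochberg adjusted p-values over the probes tested and a threshold of 0.05. Overlaps of called lists were tested with the one-sided Fisher's exact test over the probes tested. The SE of a contrast is that of limma, with its moderated spread. Changes of known size were added to simulated data for 200 of 32121 probes in the adult Tabby arrays to test recovery: 55.5% of 1.5-fold, 90% of 2-fold and 100% of 4-fold changes were called with the right sign, 0 with the wrong sign, beside 4 to 7 false calls. The simulated noise was independent between probes and equal in all groups. In the real data the Tabby adult replicates differed with an SD of 0.309 in log2, more than any group but Tabby E17.5. These rates may thus be too favourable for the adult comparison.

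Named probes were chosen by rank among those with an adjusted p under 0.05. For the mean over 5 stages, they had the largest change in each direction and the same sign at 5 of 5 stages. For a single stage, they had the largest change in each direction with both Tabby arrays on the same side of both WT arrays. For genotype by stage, they had the smallest adjusted p. For WT adult minus WT E17.5, and for WT adult minus WT P5, they had the largest change in each direction with the arrays of both groups separated. Up to 2 probes were named per direction, and a probe that 2 comparisons chose counts under both. The rule as first written passed over clone identifiers and named more genes. Since 0 of the probes carried any other name, this exclusion was dropped and the number lowered after the files were seen. Probes outside this rule are said to have been chosen after their values were seen. A fold is given as a bound where 1 of the groups compared had 0 arrays well above background, taken from the Cy3 channel against the lowest Cy3 signal well above background on each array. It was computed with the Cy3 signals normalized alone and with those normalized with Cy5, and the smaller is given.

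Alternatives were the processed signals of the scanner software, no background subtraction, the Cy3 channel alone with quantile normalization, scale normalization between arrays, the deposited value table, no filter on dim probes or a filter of 10 arrays, a trended robust fit, array weights, a minimum change of 1.5-fold, a fit of the compared groups alone, the replicate number as a block, and leaving out each array in turn. The groups, tests and these alternatives were fixed before the data were examined. A correction for probe GC content in 9 bins, the omission of single arrays from comparisons of other groups, the mean over E17.5 and adult stages only, and the comparisons of WT adult with WT P5 and of WT P5 with WT P1 were added afterwards. Lists of genes had been fixed too, among them potassium channel, chloride channel, sweat gland and sex-linked genes, the last for the sex of the animals. So had the gene of ectodysplasin A and a summary of probes by gene. All were left out because the probe identifiers could not be linked to gene names here.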

Results

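RNA from mouse footpad skin was measured on 20 two-colour oligonucleotide arrays, 2 for each of 10 groups: wild-type (WT) and Tabby mice before birth (E17.5), at postnatal days 1, 3 and 5 (P1, P3 and P5) and as adults at postnatal day 56. Footpads carry the eccrine sweat glands of the mouse, and Tabby mice carry a mutation of the gene for ectodysplasin A, without which these glands do not form. Per the series title, the study was about potassium and chloride channels in these glands. On every array the footpad RNA was labelled with Cy3 and a common reference RNA with Cy5, so that a higher log2 ratio means more signal in the footpad relative to the reference. Each array held 42006 distinct probes of 60 bases, and 32121 of them were tested. Per array, 27199 to 30273 probes had a Cy3 signal well above background. The files named probes by Z-number identifiers with their sequences and 0 of the probes by any other name, so probes rather than genes are described and no genome position is given for them.

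Replicate arrays of a group correlated at r = 0.959 to 0.996 in the log2 ratio across probes, which are not independent replicates. The SD of the difference between the 2 replicates was 0.114 to 0.217 in log2 for 8 of the groups, 0.309 for Tabby adult and 0.425 for Tabby E17.5. Tabby E17.5 replicate 2 had 43 spots marked as outliers by the scanner software, against 1 to 11 on every other array. With 2 arrays per group, the number of arrays limited the precision of each comparison, and the spread was estimated by limma over all 20 arrays. Each stage was hybridised on its own slide of 4 arrays, with WT at positions 1 and 2 and Tabby at positions 3 and 4 on every slide. Stage and slide therefore cannot be told apart, and neither can genotype and position on the slide, while each genotype comparison lies within 1 slide.

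The comparison of Tabby with WT within a stage asked which footpad transcripts depended on the mutation at that age. The number of probes that differed at an adjusted p (limma, Benjamini-Hochberg) under 0.05 was 4 at E17.5, 11 at P1, 76 at P3, 202 at P5 and 1977 in adults. Of these, all 4 at E17.5, all 11 at P1, 71 at P3, 184 at P5 and 1390 in adults were lower in Tabby. With each stage fitted alone the counts were 0, 9, 314, 835 and 385 in the same order. With array weights they were 1, 15, 3089, 2339 and 867. In both settings the largest count was not in adults, so the rise of the count up to adults depends on how the spread was estimated.

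**Figure D1:**
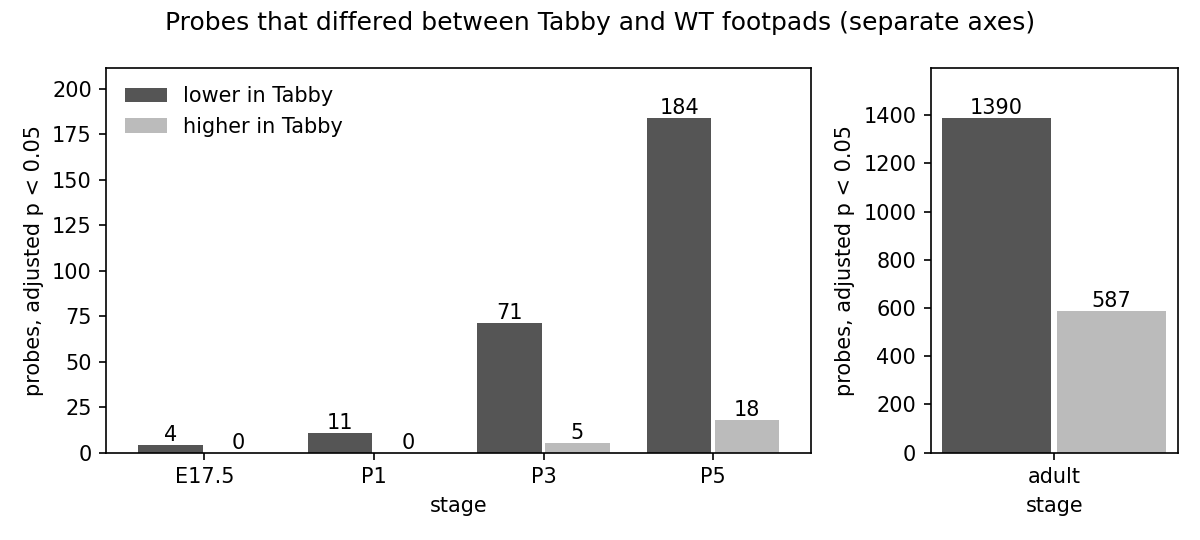
Number of probes (y axis, with a separate scale for adult) that were lower (dark bars) or higher (light bars) in Tabby than in WT footpads at each stage (x axis), at a limma adjusted p under 0.05 with 2 arrays per group. Lower probes outnumbered higher ones at each stage, with 184 against 18 at P5 and 1390 against 587 in adults. The order of the stages by count depended on how the spread was estimated.

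At E17.5, 4 probes were lower in Tabby, by a median of 2.61-fold, and 0 were higher, with 3685 probes at an unadjusted limma p under 0.05 in either direction. The lowest was Z00077373-1 (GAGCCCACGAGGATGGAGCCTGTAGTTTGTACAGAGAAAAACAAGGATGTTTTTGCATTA), with a log2 ratio of 1.76 ± 0.27 (SD, n = 2) in WT and 0.00 ± 0.00 (SD, n = 2) in Tabby. Its log2 difference was -1.77 ± 0.17 (SE, limma adjusted p = 0.00152), and its Cy3 signal was well above background on 2 WT arrays and 0 Tabby arrays. Measured against the lowest Cy3 signal that counted as well above background, Tabby was at least 2.89-fold lower. Such bounds hold for the footpad channel and remain open to dye bias, since no array had the dyes exchanged. Next came Z00036698-1 (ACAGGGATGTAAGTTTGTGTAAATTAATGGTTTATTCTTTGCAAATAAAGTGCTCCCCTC), at 1.31 ± 0.09 in WT and -0.27 ± 0.15 in Tabby (SD, n = 2 each), a difference of -1.59 ± 0.12 (SE, limma adjusted p = 8.29e-05). It was lower at each later stage too, with a difference of -1.12 in adults (limma adjusted p = 2.5e-05). All 4 probes were among the 71 that were lower at P3. This count and its balance rested on single arrays: 2 probes (0 higher) passed without Tabby E17.5 replicate 2, 7 (0 higher) without WT E17.5 replicate 1, 6 (3 higher) without WT E17.5 replicate 2 and 8195 (3086 higher) without Tabby E17.5 replicate 1, where the remaining Tabby array was the one with outlier spots. The outlier spots were set to missing and do not account for such a count. The 2 Tabby E17.5 arrays correlated at r = 0.998 in Cy3 and 0.999 in Cy5, while their log2 ratios differed with an SD of 0.425. Without background subtraction, 449 probes had an unadjusted limma p under 0.05, against 3685 here. The E17.5 result thus depends on how the ratio was computed, and the cause was not tested. With the processed signals of the scanner software 17 probes (6 higher) passed, and 21 (8 higher) with the deposited value table. These gave a difference of -2.61 each for Z00036698-1, and of -5.93 and -4.86 for Z00077373-1, whose Tabby signal was not well above background. With these 4 arrays fitted alone 0 probes passed (limma, 253 at an unadjusted p under 0.05), and both named probes had an adjusted p of 0.871. With array weights Z00077373-1 also lost the call (limma adjusted p = 0.871), while Z00036698-1 kept it (0.0137).

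At P1, 11 probes were lower in Tabby, by a median of 2.29-fold, and 0 were higher, with 1372 at an unadjusted limma p under 0.05 in either direction. Z00020870-1 (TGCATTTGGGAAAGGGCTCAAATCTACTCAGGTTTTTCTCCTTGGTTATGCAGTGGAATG) had a log2 ratio of 3.61 ± 0.00 in WT and 0.47 ± 0.24 in Tabby (SD, n = 2 each), 8.82-fold lower, with a log2 difference of -3.14 ± 0.28 (SE, limma adjusted p = 0.000307). Z00077373-1, the lowest at E17.5, differed by -2.34 ± 0.17 (SE, limma adjusted p = 4.57e-05) and was again well above background on 2 WT and 0 Tabby arrays, at least 3.38-fold lower. Its difference was -6.19 with the processed signals and -5.76 with the deposited value table. Of the 11 probes, 8 were also lower at P5 (0.063 expected for independent lists, one-sided Fisher's exact test p = 1.62e-16). Both lists use the same estimate of the spread for each probe, so they are not independent and this p-value overstates the evidence. The count was 90 (26 higher) without WT P1 replicate 2, 7 without Tabby P1 replicate 2, 31 without Tabby E17.5 replicate 2 and 18 without Tabby adult replicate 1. It was 122 with the Cy3 channel alone, of which 54.9% were lower, 113 with the deposited value table (69.9% lower) and 5 with the replicate numbers as a block.

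At P3, 71 probes were lower in Tabby, by a median of 2.12-fold, and 5 were higher. Z00025964-1 (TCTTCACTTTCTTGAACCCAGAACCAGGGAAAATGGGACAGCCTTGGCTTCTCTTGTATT) fell from a log2 ratio of 5.22 ± 0.10 in WT to 0.02 ± 0.23 in Tabby (SD, n = 2 each), a difference of -5.21 ± 0.81 (SE, limma adjusted p = 0.0124), and was well above background on 1 of 2 Tabby arrays. Z00047655-1 (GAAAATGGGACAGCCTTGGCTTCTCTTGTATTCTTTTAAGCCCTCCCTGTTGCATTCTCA), whose sequence overlaps with it, differed by -4.96 ± 0.65 (SE, limma adjusted p = 0.00311), from 4.79 ± 0.11 in WT to -0.17 ± 0.03 in Tabby (SD, n = 2 each). The SE of both is large because WT E17.5 replicates differed in them, with a log2 ratio of 1.01 ± 2.29 (SD, n = 2) for Z00047655-1. In the other direction, Z00068907-1 (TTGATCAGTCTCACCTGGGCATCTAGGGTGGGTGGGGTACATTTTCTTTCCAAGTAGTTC) rose by 0.66 ± 0.11 (SE, limma adjusted p = 0.0288), from -0.08 ± 0.01 to 0.57 ± 0.19 (SD, n = 2 each). Z00058587-1 (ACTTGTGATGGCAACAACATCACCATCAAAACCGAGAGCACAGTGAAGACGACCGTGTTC) rose by 0.60 ± 0.10 (SE, limma adjusted p = 0.015), from 1.57 ± 0.04 to 2.17 ± 0.04 (SD, n = 2 each). It was also higher at P5 (0.54, limma adjusted p = 0.0162) and in adults (0.40, limma adjusted p = 0.0276). The count of 76 was 24 (1 higher) without WT P3 replicate 1, 42 (2 higher) without WT P3 replicate 2, 31 (4 higher) and 34 (3 higher) without Tabby P3 replicate 1 and 2, 198 (38 higher) without Tabby E17.5 replicate 2 and 121 (17 higher) without Tabby adult replicate 1. The calls of Z00025964-1 and Z00058587-1 were lost without any 1 of the 4 P3 arrays (limma adjusted p = 0.119 to 0.192 and 0.119 to 0.301), that of Z00068907-1 without 3 of them (0.257 to 0.484), and that of Z00047655-1 without WT P3 replicate 1 (0.0709) or Tabby P3 replicate 1 (0.0549). Z00025964-1 also lost it with the processed signals (difference -5.98, adjusted p = 0.0753) and the replicate block (0.162), Z00068907-1 with the processed signals (difference 1.39, 0.0503) and the Cy3 channel alone (0.0635), and Z00058587-1 with scale normalization (1) and the trended robust fit (0.107). Counts reached 287 with the deposited value table (64.1% lower), 713 with the Cy3 channel alone (60.3% lower) and 3089 with array weights (56% lower), against 93.4% lower here.

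At P5, 184 probes were lower in Tabby, by a median of 2.19-fold and by at least 4-fold for 42 of them, and 18 were higher. Z00047655-1 showed the largest fall of any probe named at this stage, from 6.47 ± 0.11 in WT to 0.87 ± 0.12 in Tabby (SD, n = 2 each), 48.2-fold, with a difference of -5.59 ± 0.65 (SE, limma adjusted p = 0.000256). At P1 this probe gave 0.00 ± 0.00 in WT and -0.11 ± 0.01 in Tabby (SD, n = 2 each), and in adults 0.37 ± 0.18 and 0.47 ± 0.19 (SD, n = 2 each). Z00050873-1 (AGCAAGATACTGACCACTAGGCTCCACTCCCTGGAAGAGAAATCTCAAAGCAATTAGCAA) fell from 5.79 ± 0.06 to 1.14 ± 0.12 (SD, n = 2 each), a difference of -4.65 ± 0.51 (SE, limma adjusted p = 0.000168). Higher in Tabby was Z00025066-1 (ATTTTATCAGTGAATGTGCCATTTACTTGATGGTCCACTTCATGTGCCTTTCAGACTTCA), by 1.90 ± 0.31 (SE, limma adjusted p = 0.00713), from -0.30 ± 0.03 to 1.60 ± 0.05 (SD, n = 2 each). Z00025781-1 (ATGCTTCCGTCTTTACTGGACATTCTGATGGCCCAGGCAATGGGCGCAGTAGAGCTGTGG) was higher by 1.5 ± 0.23 (SE, limma adjusted p = 0.00414), from 0.18 ± 0.21 to 1.68 ± 0.06 (SD, n = 2 each). The count of 202 was 125 (2 higher) without WT P5 replicate 1, 137 (1 higher) without WT P5 replicate 2, 142 (10 higher) and 126 (5 higher) without Tabby P5 replicate 1 and 2, and 314 (61 higher) without Tabby E17.5 replicate 2. The higher side thus rested on single arrays. Z00025066-1 lost the call without any 1 of the 4 P5 arrays (adjusted p = 0.0755 to 0.0903), as did Z00025781-1 without WT P5 replicate 2 (0.0866) or Tabby P5 replicate 2 (0.0662). With the Cy3 channel alone, the difference was -6.72 for Z00047655-1 and -5.58 for Z00050873-1. With the processed signals Z00050873-1 lost the call (-3.89, adjusted p = 0.0922), with scale normalization Z00025066-1 (0.264) and Z00025781-1 (0.977), and with the replicate block Z00025066-1 (0.0838). The count was 305 with the deposited value table (80.7% lower), 448 with the Cy3 channel alone (65.2% lower), 835 with the P5 arrays fitted alone (56.5% lower) and 2339 with array weights (51.3% lower), against 91.1% lower here.

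In adults, 1390 probes were lower in Tabby, by a median of 1.52-fold, with 371 at least 2-fold and 116 at least 4-fold lower. Another 587 were higher, by a median of 1.35-fold, with 37 at least 2-fold higher. The 1977 probes were 6.15% of those tested. Z00025366-1 (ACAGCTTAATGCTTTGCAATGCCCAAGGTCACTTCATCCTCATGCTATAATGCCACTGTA) fell from 3.97 ± 0.30 in WT to -0.98 ± 0.78 in Tabby (SD, n = 2 each), 30.9-fold, with a difference of -4.95 ± 0.26 (SE, limma adjusted p = 2.21e-08). Its difference was -1.74 at P3 (limma adjusted p = 0.00821) and -3.23 at P5 (limma adjusted p = 5.1e-06). Z00074275-1 (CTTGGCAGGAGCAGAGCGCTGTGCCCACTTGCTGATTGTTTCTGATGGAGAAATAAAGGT) fell from 4.58 ± 0.01 to -0.19 ± 0.87 (SD, n = 2 each), a difference of -4.76 ± 0.26 (SE, limma adjusted p = 3.35e-08). Its difference was -0.68 at P5 (limma adjusted p = 0.541). Higher in Tabby was Z00031876-1 (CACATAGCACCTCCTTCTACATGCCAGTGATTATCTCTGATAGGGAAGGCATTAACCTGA), by 2.67 ± 0.57 (SE, limma adjusted p = 0.0129), from 1.11 ± 0.39 to 3.78 ± 1.98 (SD, n = 2 each), so that its Tabby replicates lay far apart. Z00006534-1 (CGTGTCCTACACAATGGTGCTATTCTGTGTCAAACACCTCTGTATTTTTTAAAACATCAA) was higher by 2.01 ± 0.16 (SE, limma adjusted p = 1.59e-06), from -0.21 ± 0.06 to 1.80 ± 0.40 (SD, n = 2 each).

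Of the 1390 probes lower in adult Tabby footpads, 59 were well above background on neither Tabby array, and 0 were so on neither WT array. Probes that share at least 30 bases sit at different places on the array, and of 58 such pairs with a call in adults 57 differed from WT in the same direction, 41 with both probes called and 0 with calls in opposite directions. With the Cy3 channel alone, 1639 of the 1977 probes were called in the same direction and 6 had the opposite sign. The count of 1977 was 806 (101 higher) without WT adult replicate 1, 4323 (2091 higher, 51.6% lower) without Tabby adult replicate 2 and 3165 (1142 higher) without Tabby E17.5 replicate 2, with Z00031876-1 losing the call without WT adult replicate 1 (adjusted p = 0.138). That probe differed by 1.26 without Tabby adult replicate 1 and by 4.07 without replicate 2, and it lost the call with the adult arrays fitted alone (adjusted p = 0.37) and with the processed signals (0.0698). Z00006534-1 lost the call with scale normalization (1.91, adjusted p = 0.62). The difference of Z00025366-1 was -5.83 with the processed signals. That of Z00074275-1 was -5.42 with the deposited value table, and -4.15 and -5.38 without Tabby adult replicate 1 and 2. The count was 385 with the adult arrays fitted alone (95.6% lower), 867 with array weights, 828 with arrays brought to 1 scale (81.8% lower), 2957 with the processed signals (61.3% lower), 2916 with the deposited value table (1313 higher, 55% lower), 3457 with the Cy3 channel alone (56.6% lower) and 3797 without background subtraction (60.8% lower), against 70.3% lower here.

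Most lists of lower probes overlapped between stages, but the E17.5 and adult lists shared 1 probe (0.173 expected, one-sided Fisher's exact test p = 0.162, Benjamini-Hochberg 0.249). The P3 and P5 lists shared 53 probes (0.407 expected for independent lists, one-sided Fisher's exact test p = 1.1e-106, Benjamini-Hochberg 2.2e-105 over 20 overlaps). The P5 and adult lists shared 58 (7.96 expected, one-sided Fisher's exact test p = 5.21e-34, Benjamini-Hochberg 5.21e-33). Probes are not independent of each other, so these p-values overstate the evidence. The lists of all stages also use the same estimate of the spread for each probe, which favours the same probes at several stages. Among higher probes, 3 of the 18 at P5 were higher in adults too (0.329 expected, one-sided Fisher's exact test p = 0.00404, Benjamini-Hochberg 0.00673). The overlap of 53 was 21 and 29 without WT P3 replicate 1 and 2, 24 and 25 without Tabby P3 replicate 1 and 2 and 87 without Tabby E17.5 replicate 2. It was 35 with the replicate numbers as a block and 422 with array weights.

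Of the 1530 probes lower in Tabby at any stage, 140 were lower at 1 or more of the stages from E17.5 to P5 and not called in adults, 65 were lower both before and in adults, and 1325 were called lower in adults alone. In the first group of 140, the median log2 Cy3 signal of WT footpads was 6.665 at P1, 7.084 at P3, 7.941 at P5 and 6.638 in adults, while that of Tabby footpads lay between 6.586 and 6.69 at these 4 stages. On this scale the lowest signal that counted as well above background was 6.03 to 6.17 on the Tabby arrays of these stages. Of the 140 probes, 35 were well above background on neither Tabby P5 array, 39 on neither Tabby adult array and 39 on neither WT adult array, so that the Tabby medians lie near the floor of detection. In the group of 65, the WT median was 8.33 at E17.5, 9.566 at P5 and 10.56 in adults, and the Tabby median was 8.048, 8.093 and 7.805 at the same stages. In the group of 1325, the median log2 difference was -0.59 in adults and -0.062 at P5, a contrast that the choice of these probes favours. Of the 1325, 484 had a genotype effect called more negative in adults than at P5, and 414 were called for genotype by stage. At P3, 65.6% of them had a negative difference, against 49.5% of all probes. A missing call before adults thus does not show that the difference was absent there.

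**Figure D2:**
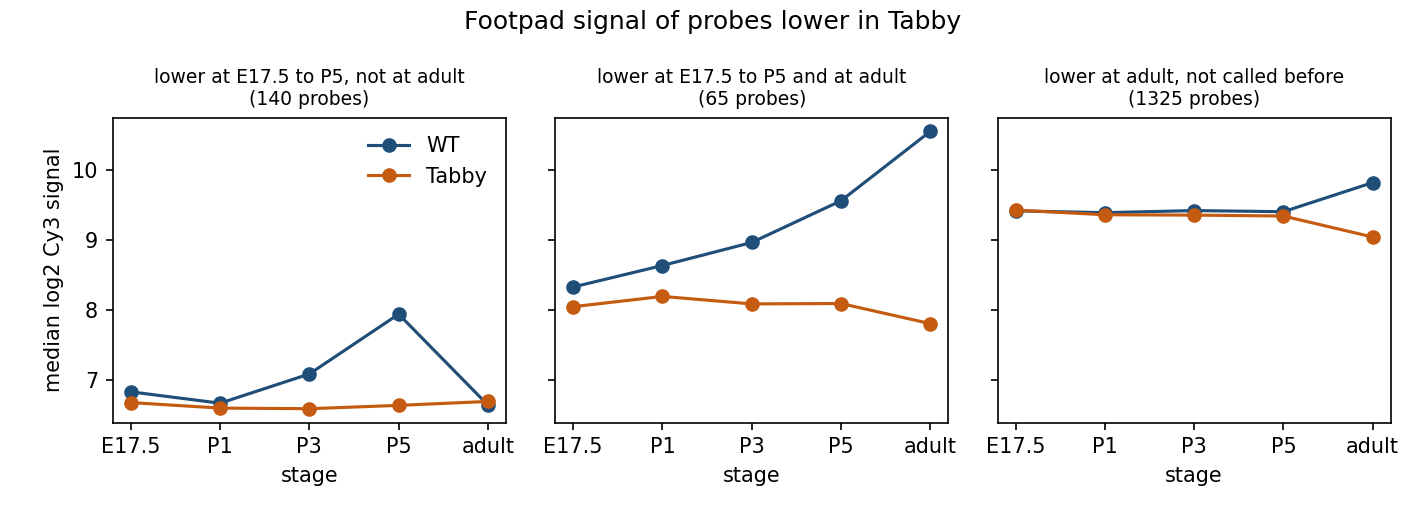
Median log2 Cy3 signal (y axis) of WT and Tabby footpads at each stage (x axis) over the probes called lower in Tabby from E17.5 to P5 and not in adults (140), at both (65) and in adults alone (1325). Points are medians over probes of the means of 2 arrays, and in the first group WT lay at 7.941 at P5 and at 6.638 in adults.

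Because probes were put in these groups by the same arrays, the WT course was also measured on arrays left out of the choice. Probes called lower at P5 without WT P5 replicate 1 (123) lay in that array above the WT P1 mean by a median log2 of 1.3, with 97.6% above 0, against 51.2% of all probes tested. Without WT P5 replicate 2 (136 probes) the median was 1.1, with 96.3% above 0 against 51%. Probes called without Tabby P5 replicate 1 (132) and without replicate 2 (121) lay in the Tabby array left out at a median of -0.0017 and -0.0091 from the Tabby P1 mean, with 49.2% and 48.8% above 0. Probes called lower in adults without WT adult replicate 1 (705) and without replicate 2 (1165) lay in the array left out above the WT P5 mean by a median of 0.72 and 0.33, with 77% and 66.5% above 0. Those called without Tabby adult replicate 1 (1063) and without replicate 2 (2232) lay in the Tabby array left out at a median of -0.088 and -0.15 from the Tabby P5 mean, with 45.9% and 40.5% above 0. The differences of these shares from those of all probes were not tested.

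Averaged over the 5 stages, 1280 probes were lower in Tabby, by a median of 1.19-fold, and 389 were higher, at a limma adjusted p under 0.05. Z00020870-1 had a negative difference at 5 of 5 stages, with a mean of -2.64 ± 0.13 (SE, limma adjusted p = 3.97e-08). The mean was -1.97 with the processed signals and with the deposited value table, -1.96 with E17.5 and adult stages only, and -3.44 with the Cy3 channel alone. Its log2 ratio in WT was 2.22 ± 0.28 at E17.5, 5.44 ± 0.14 at P5 and 5.97 ± 0.08 in adults (SD, n = 2 each). Z00062492-1 (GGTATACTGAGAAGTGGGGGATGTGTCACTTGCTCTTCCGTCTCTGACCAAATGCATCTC) also had a negative difference at 5 of 5 stages, with a mean of -2.24 ± 0.07 (SE, limma adjusted p = 3.18e-10), and of -2.89 with the processed signals. The difference of this probe was -0.56 at E17.5 (limma adjusted p = 0.433), -1.56 at P1 (limma adjusted p = 4e-04), -2.26 at P3 (limma adjusted p = 4.85e-06), -2.73 at P5 (limma adjusted p = 9.45e-08) and -4.10 in adults (limma adjusted p = 7.71e-10). Positive at 5 of 5 stages was the difference of Z00024255-1 (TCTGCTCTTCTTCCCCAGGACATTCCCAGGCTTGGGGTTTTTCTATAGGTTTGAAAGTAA), with a mean of 0.69 ± 0.18 (SE, limma adjusted p = 0.0432). The same held for Z00000460-1 (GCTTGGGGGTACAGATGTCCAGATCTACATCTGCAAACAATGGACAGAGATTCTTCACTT), with a mean of 0.67 ± 0.18 (SE, limma adjusted p = 0.0414). Both lost the call with array weights (adjusted p = 0.175 and 0.17), with the replicate numbers as a block (0.107 and 0.0956), with E17.5 and adult stages only (0.284 and 0.286), with scale normalization (0.193 and 0.16), with the processed signals (0.0529 and 0.0573) and without single arrays, such as Tabby E17.5 replicate 2 (0.0545 and 0.0522). The count of 1669 was 5833 without Tabby E17.5 replicate 1, 2874 without Tabby adult replicate 2, 2605 without WT P1 replicate 2 and 1015 without WT E17.5 replicate 2. It was 1065 and 1057 without WT P3 replicate 1 and 2, 1095 without Tabby P3 replicate 1, 1087 and 1058 without WT P5 replicate 1 and 2, and 1105 and 1088 without Tabby P5 replicate 1 and 2. Other settings gave 1072 with E17.5 and adult stages only, 729 with arrays brought to 1 scale and 3604 with the Cy3 channel alone (56.6% lower, against 76.7% here).

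**Figure D3:**
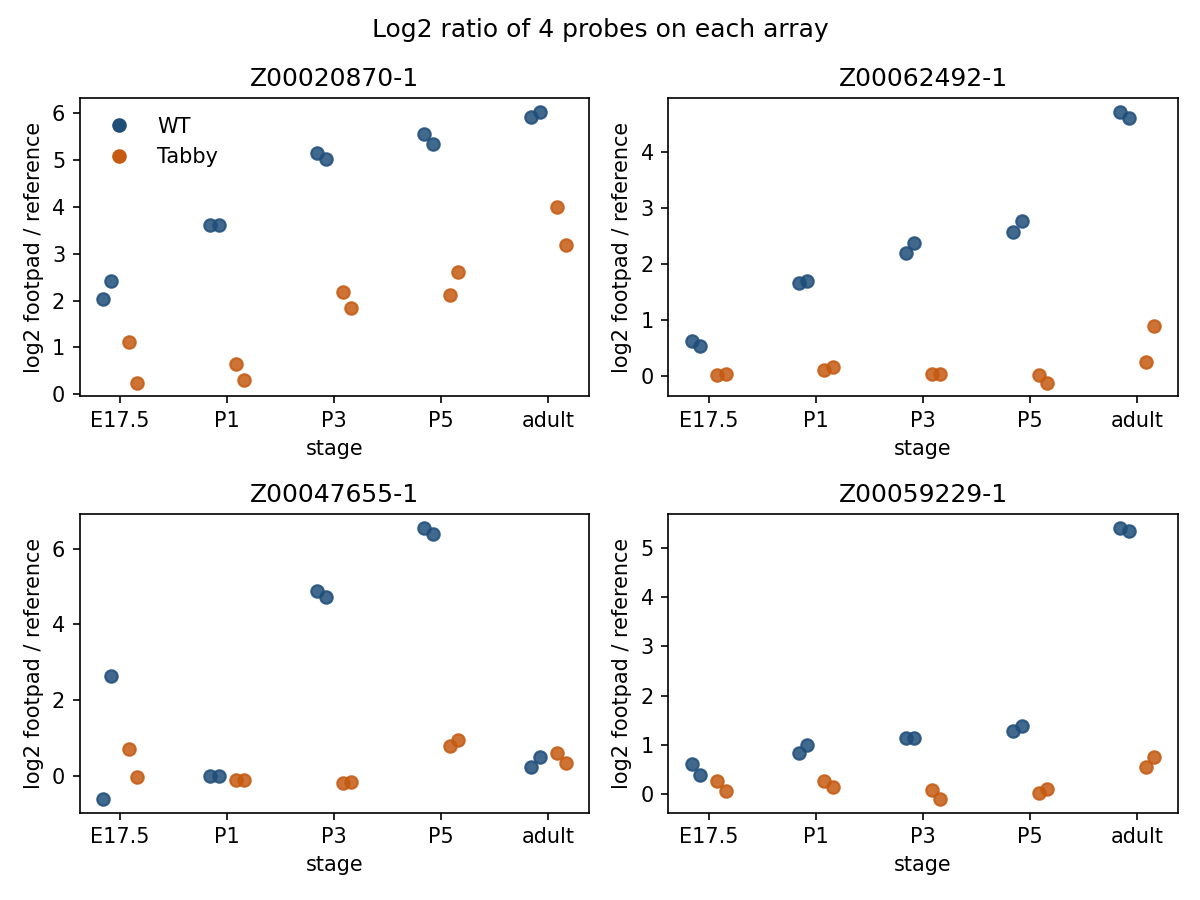
Log2 ratio of footpad over reference (y axis) on each of the 20 arrays (points) for 4 named probes by stage (x axis) in WT and Tabby. Z00020870-1 and Z00062492-1 had a negative difference at 5 of 5 stages, Z00047655-1 differed by -4.96 at P3 and -5.59 at P5, and Z00059229-1 by -4.73 in adults.

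The test of genotype by stage asked whether the difference between Tabby and WT changed with age, and called 610 probes (1.9% of those tested; limma, adjusted p under 0.05). Z00059229-1 (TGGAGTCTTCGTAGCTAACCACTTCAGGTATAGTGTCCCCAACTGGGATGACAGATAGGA) had the smallest adjusted p (limma, 2.36e-08), with differences of -0.34 at E17.5 and -4.73 in adults. At P1, P3 and P5 it was well above background on 2 WT and 0 Tabby arrays, at least 1.42-fold, 1.77-fold and 1.99-fold lower in Tabby. In adults its log2 ratio was 5.38 ± 0.04 in WT and 0.66 ± 0.14 in Tabby (SD, n = 2 each). Z00047237-1 (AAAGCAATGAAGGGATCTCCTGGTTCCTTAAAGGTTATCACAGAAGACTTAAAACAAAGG) followed (limma adjusted p = 3.22e-08), with a difference of -4.01 in adults. From E17.5 to P5 it was well above background on 1 WT P1 array and on no other array, so its genotype difference at these stages was not detectable. Between single stages, 693 probes had a different genotype effect in adults than at P5, 533 of them more negative in adults. Another test called 92 probes with a different effect at P5 than at P1, 91 of them more negative at P5. The count of 610 was 382 without WT adult replicate 1, 1472 without Tabby adult replicate 2 and 6406 without Tabby E17.5 replicate 1. Of the 610 probes, 545 were also called with the Cy3 channel alone, which called 1015 in all. The count was 403 with the replicate numbers as a block, 335 with array weights, 1107 with the deposited value table and 1158 without background subtraction.

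At P1, P3 and P5, the genotypes also differed in a probe that was chosen after its values were seen. The log2 Cy3 signal of Z00016441-1 (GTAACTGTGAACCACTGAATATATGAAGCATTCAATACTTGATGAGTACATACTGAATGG) was 11.09 to 11.52 on all 6 Tabby arrays of these stages and 12.25 on WT E17.5 replicate 1, and 6.07 to 6.92 on the other 13 arrays. At P1, P3 and P5 it was well above background on 2 Tabby and 0 WT arrays, at least 39-fold, 32.1-fold and 34.7-fold higher in Tabby, and in adults on 0 arrays of either genotype. The limma adjusted p-values at P1, P3 and P5 were 0.251, 0.11 and 0.0601, with a spread that includes the E17.5 replicates, and that of the mean over 5 stages was 0.00613. Z00002110-1 (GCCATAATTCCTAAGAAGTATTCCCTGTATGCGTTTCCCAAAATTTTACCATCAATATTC), also chosen after its values were seen, went the other way, with a log2 Cy3 signal of 7.54 on WT E17.5 replicate 1, 7.78 to 7.95 on the 6 Tabby arrays and 8.15 to 8.82 on the other 13. It passed at no stage, with limma adjusted p-values of 1, 0.294 and 0.405 at P1, P3 and P5 and 0.112 for the mean over 5 stages. The WT and Tabby samples at P1, P3 and P5 thus differed in a signal that did not separate the genotypes in adults, and each genotype comparison at these stages includes that difference. Z00064853-1, given under other observations, was lower on the same arrays as Z00002110-1. The labels give no sex of the animals, and whether sex differed between these samples was not tested.

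**Figure D4:**
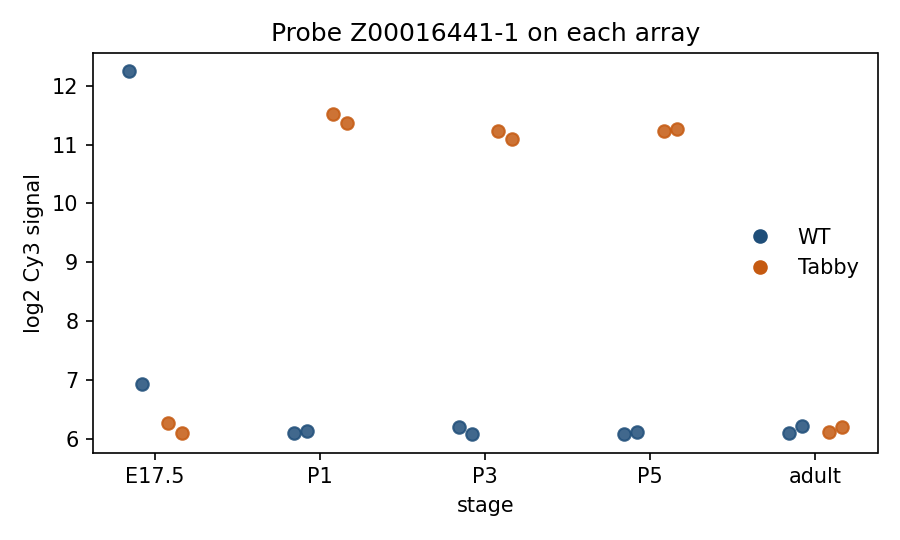
Log2 Cy3 signal (y axis) of probe Z00016441-1 on each of the 20 arrays (points) by stage (x axis) in WT and Tabby. The signal lay at 11.09 to 11.52 on the 6 Tabby arrays of P1, P3 and P5 and at 12.25 on 1 WT array of E17.5, and at 6.07 to 6.92 on the rest.

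The course of WT footpads from E17.5 to the adult was the last comparison, and the log2 ratio of 25573 probes (79.6% of those tested) changed with stage (limma, adjusted p under 0.05). Of these, 21858 were also called with the Cy3 channel alone. Between WT adult and WT E17.5, 11455 probes were higher and 10607 lower in adults. Z00034035-1 (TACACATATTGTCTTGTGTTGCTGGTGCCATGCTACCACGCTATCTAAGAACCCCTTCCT) fell from 4.30 ± 0.00 to -5.16 ± 0.09 (SD, n = 2 each), a change of -9.46 ± 0.20 (SE, limma adjusted p = 3.18e-13). Z00037787-1 (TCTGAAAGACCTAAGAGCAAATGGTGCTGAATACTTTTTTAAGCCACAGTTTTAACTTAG) changed by -9.37 ± 0.23 (SE, limma adjusted p = 7.71e-13). Z00023589-1 (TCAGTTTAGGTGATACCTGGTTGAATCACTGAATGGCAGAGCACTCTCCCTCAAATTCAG) rose from 0.47 ± 0.14 to 8.24 ± 0.38 (SD, n = 2 each), by 7.77 ± 0.33 (SE, limma adjusted p = 1.27e-10). It stood at 7.35 ± 0.05 at P1 and 1.88 ± 0.86 at P3 (SD, n = 2 each). Z00023218-1 (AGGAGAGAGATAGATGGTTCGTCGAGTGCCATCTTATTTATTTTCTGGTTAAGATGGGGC) rose by 7.55 ± 0.18 (SE, limma adjusted p = 8.39e-13). With the Cy3 channel alone, Z00034035-1 changed by -8.75 and Z00037787-1 by -7.50. With scale normalization the 4 probes changed by -8.66, -8.57, 7.14 and 6.92, and Z00023589-1 changed by 6.66 with the processed signals and with the deposited value table. In each of these 4 probes, Tabby differed from WT by no more than 0.39 in absolute log2 at E17.5 and in adults, with limma adjusted p-values of 0.435 to 0.989. Between these stages the difference reached 1.28 at P5 for Z00023589-1 (limma adjusted p = 0.17) and 0.81 at P3 for Z00023218-1 (limma adjusted p = 0.123).

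The reference channel of the E17.5 slide differed from that of the other slides. The log2 Cy5 signal of its arrays correlated across probes at r = 0.961 to 0.965 with arrays of other slides, against 0.993 to 0.999 between the other slides and 0.997 to 0.999 within a slide. Between WT P1 and WT E17.5, the SD of the change over probes was 0.736 for the log2 ratio, 0.725 for the Cy5 channel and 0.435 for the Cy3 channel. Of the 22062 probes called between WT adult and WT E17.5, 3460 (15.7%) had the opposite sign with the Cy3 channel alone and 14792 were called in the same direction by both. The Cy5 channel alone called 21862 probes between these 2 groups. Comparisons with E17.5 in the log2 ratio, among them the test over stages with its 25573 probes, therefore mix the footpad with the reference. A comparison of later stages was added after the data were seen.

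**Figure D5:**
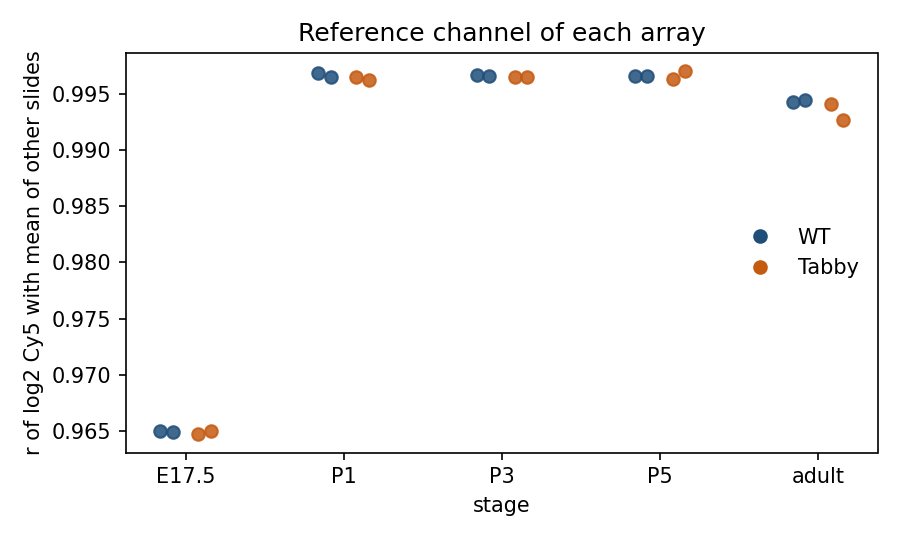
Pearson's r across probes of the log2 Cy5 (reference) signal of each array with the mean of the arrays on other slides (y axis) by stage, each on its own slide (x axis). The 4 arrays of E17.5 lie at 0.9647 to 0.965 and all 16 others at 0.9927 or above.

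Between WT adult and WT P5, 8649 probes were higher and 8479 lower in adults, of which 84 had the opposite sign with the Cy3 channel alone. Z00034035-1 changed by -8.39 ± 0.20 (SE, limma adjusted p = 4.85e-12), and by -7.78 with the Cy3 channel alone. Z00018229-1 (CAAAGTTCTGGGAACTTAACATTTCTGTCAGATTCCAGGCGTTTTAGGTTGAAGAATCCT) was well above background on 2 P5 and 0 adult arrays, at least 106-fold lower in adults. Z00022843-1 (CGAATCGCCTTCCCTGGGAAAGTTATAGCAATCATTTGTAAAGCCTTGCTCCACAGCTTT) rose from -3.18 ± 0.00 to 2.97 ± 0.29 (SD, n = 2 each), by 6.15 ± 0.34 (SE, limma adjusted p = 5.34e-09), and by 7.29 with the processed signals and with the deposited value table. Z00023589-1 rose by 6.12 ± 0.33 (SE, limma adjusted p = 3.76e-09), by 3.57 with those 2 alternatives and by 5.44 with scale normalization. Between WT P5 and WT P1, 3263 probes were higher and 2772 lower at P5. In all 6035 were called, 2667 without WT P5 replicate 1, 2823 without WT P5 replicate 2 and 3089 without WT P1 replicate 2. Among the 3 stages scanned on 1 day, 5609 probes differed between WT P3 and WT P1 and 276 between WT P5 and WT P3. For WT adult minus WT P5, the SD of the change over probes was 0.239 for the Cy5 channel, with 1442 probes called, against 0.799 for the Cy3 channel. A difference between slides that both channels share is thus too small to be the whole of these changes. A difference between slides in the Cy3 labelling alone cannot be told apart from stage.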

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

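The tests of an on/off difference between the animals, of array position, of an exchange of arrays over the probes lower at P1, of a different reference and of signal leaking between channels were chosen only after the result was seen, as were the comparisons of the genotype effect between adults and P5 and between P5 and P1. The genotype effect differed between stages for 610 probes (limma, adjusted p under 0.05), with adjusted p-values of 2.36e-08 for Z00059229-1 and 3.22e-08 for Z00047237-1, whose Tabby minus WT differences in adults were -4.73 and -4.01. Between single stages, the test of the difference called 693 probes in adults against P5 and 92 at P5 against P1.

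Probes lower in Tabby at P5 form the first pattern: 184 probes with a median log2 difference of -1.1. Because Z00016441-1 separated the Tabby from the WT arrays at P1, P3 and P5, a difference between the animals that is constant over these stages might account for them. The median difference of the 184 probes at P1 was -0.089 (quartiles -0.3 and 0.03), and 91 of the 92 probes with a different effect at P5 than at P1 were more negative at P5. In probes with ample signal at P1, neither a constant difference nor an offset of array position equal on every slide gives this. The median log2 Cy3 signal of the 184 at P1 was 6.955 in WT and 6.847 in Tabby, against 8.257 in WT at P5. The lowest signal well above background on the P1 arrays was 6.1 to 6.17. A difference can be hidden in probes that are dim at P1, so for them both explanations stay open. At P3 the median of the 184 was -0.4 (quartiles -0.9 and -0.086), with 85.9% below 0 against 49.5% of all probes, which an offset on the P5 slide alone does not give. An exchange of WT E17.5 replicate 1 with a Tabby sample was examined over the 11 probes lower at P1. In that array they lay above the Tabby E17.5 mean by a median of 0.48 (quartiles 0.21 and 1.2), against 0.49 in replicate 2 and 0.042 for all probes. The 71 lower at P3 do not decide, with 0.12 and 73.2% above that mean (replicate 2 0.22 and 87.3%, all probes 62.4%). The spread used to call both lists includes the E17.5 arrays, which favours probes in which the WT E17.5 replicates are alike. The 11 probes thus argue against an exchange only weakly. The rule first written asked for a median above 0 and a set share of probes above the Tabby E17.5 mean, and the 71 probes met it. It was replaced after the values were seen, because all probes tested met it as well. The loss of a WT rise between P1 and P5 in Tabby is a hypothesis that these tests leave standing, while an offset of position in Cy3 on both the P3 and P5 slides, on which the Cy5 median of -0.065 does not bear, and an unrecorded difference between the animals that changes with age stay open.

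The reference channel of the E17.5 slide is the second pattern. Its change from E17.5 to P1 was nearly the same probe by probe in the WT and the Tabby arrays (r = 0.984 across probes), which is consistent with another batch or labelling of the reference RNA on that slide, although both belong to 1 slide and a scan day of its own. Brightness accounted for 0.76% of the variance of the change, GC content for 0.2% and the Cy3 change, as leaking footpad signal would, for 4.3%. No biological explanation was tested, since the reference holds no footpad RNA. What differed on that slide beyond its stage cannot be told apart, and genotype comparisons within it share the same reference.

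The spread between the Tabby adult replicates is the third pattern: 27 probes were over 2 higher in log2 Cy3 in replicate 1 and 7 in replicate 2, against at most 6 in either replicate of every other group. Faults of single spots are argued against by pairs of probes that share bases, whose differences between these replicates correlated at r = 0.93 across 673 pairs, and the reference channel accounted for a median of -4.2% of the difference. A difference in RNA between the 2 adult Tabby samples, in the animals or in what was dissected, may remain, and the design gives no group to test it. The 1977 calls in adults became 1638 without Tabby adult replicate 1 and 4323 without replicate 2.

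For the mean over 5 stages, the 1669 calls were set against chance: 1 of 100 splits of the arrays within slides, the real one, gave as many, and the highest of the others gave 738. That other split parted the genotypes at 4 stages. Since 100 splits cannot show a share under 1 in 100, chance is made unlikely for the count but not excluded, and single calls are not tested. Every split kept the slides whole in stage, so that position on the slide, which follows genotype, is not tested by them.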

How the results depend on the processing

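Added after the data were seen were the GC correction, the E17.5 and adult stages only, the omission of arrays from comparisons of other groups, and the 2 later WT comparisons. Of 269 counts under alternatives, 179 lay within 1.5 times the count reported, 42 were lower and 48 higher. Of 596 values of named probes, 519 kept direction and call, 77 kept the direction and lost the call, and 0 changed direction. Those at the minimum fold repeat the values of the main fit and could not change. Most named probes were picked for large differences, so a change of direction was unlikely from the start. Except for the minimum fold, which removes calls from the counts by construction, the cause of a change was not tested.

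With the processed signals of the scanner software, 17 probes were called at E17.5, 18 at P1 and 116 at P3. Without background subtraction the counts were 7 at E17.5, 60 at P1, 388 at P3, 382 at P5, 3797 in adults, 3293 over 5 stages, 1158 for genotype by stage, 119 for the overlap of P3 with P5 and 9490 for WT P5 minus P1. With the Cy3 channel alone they were 7, 122, 713, 448 and 3457 at the 5 stages, 3604 over them, 1015 for genotype by stage and 128 for the overlap. With arrays brought to 1 scale they were 828 in adults, 729 over 5 stages and 3029 for WT P5 minus P1. The deposited value table (19626 probes) gave 21, 113, 287 and 305 from E17.5 to P5, 2514 over 5 stages, 1107 for genotype by stage and 85 for the overlap. Array weights gave 1 at E17.5, 3089 at P3, 2339 at P5, 867 in adults, 335 for genotype by stage and 422 for the overlap. A change of at least 1.5-fold, which removes smaller ones, left 886 in adults, 165 over 5 stages, 13797 for WT adult minus E17.5, 9135 for WT adult minus P5 and 1979 for WT P5 minus P1. Fitted on their own groups, 0 passed at E17.5 (limma, 253 at an unadjusted p under 0.05), 314 at P3, 835 at P5 and 385 in adults. E17.5 and adult stages only gave 1072.

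The share of lower probes shifted with the signals and scaling used and with how the spread was estimated. At E17.5 it was 100% as reported, 64.7% with processed signals, 71.4% with the Cy3 channel alone and 61.9% with the deposited table, and at P1 100%, 94.4%, 54.9% and 69.9%. In adults it was 70.3% as reported, 56.6% with the Cy3 channel alone and 81.8% with arrays brought to 1 scale. At P3 it was 93.4%, 60.3% with Cy3 alone and 64.1% with the deposited table, and at P5 91.1%, 65.2% and 80.7%. With array weights the share was 56% at P3, 51.3% at P5 and 86.7% in adults. Fits on own groups gave 76.8%, 56.5% and 95.6% in the same order.

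The replicate block gave 5 calls at P1, 403 for genotype by stage and 35 for the overlap, with 3 at E17.5, 51 at P3, 169 at P5, 1512 in adults and 1154 over 5 stages. The deviation of replicate 1 from its group mean correlated across probes between WT and Tabby at r = 0.091, 0.04, -0.072, 0.13 and 0.22 from E17.5 to adult. The numbers were therefore not taken to pair the samples.

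Leaving out single arrays, where a lone array is assumed to vary like the other groups, gave 2 to 8195 at E17.5, 7 to 90 at P1, 24 to 198 at P3, 125 to 314 at P5, 806 to 4323 in adults, 1015 to 5833 over 5 stages, 382 to 6406 for genotype by stage and 21 to 87 for the overlap. For WT the ranges were 19506 to 23207 for WT adult minus E17.5, 13938 to 18672 for WT adult minus P5, 2667 to 8196 for WT P5 minus P1 and 23704 to 26930 for WT over stages. Except for the mean over 5 stages and genotype by stage, not every array was left out: the ranges cover the arrays of the groups compared and up to 3 others. At P3, at P5, for the overlap and for each of these WT comparisons, the highest count among the arrays left out came without Tabby E17.5 replicate 2. Signal over background limits the dim probes: no filter tested 42004 and the stricter filter 28442.

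Not run were the mean of the probes of a gene, the tests of gene lists and their alternatives, since probes could not be linked to gene names, and a fit on own groups for the mean over 5 stages and genotype by stage, which already use every group.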

Other observations

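The test of a delay over probes that change in WT was chosen only after the result was seen, as were the probes named for their replicates. In 26 probes Tabby was lower at 3 or more stages, and 96 at 2 or more. Over the 26, the median log2 Cy3 signal of WT footpads was 8.614 at E17.5, 9.445 at P3 and 9.979 in adults, and that of Tabby footpads 8.35, 8.178 and 8.356. The 587 probes higher in adult Tabby had a median difference of 0.44 in adults, 0.059 at P5 and -0.015 at E17.5.

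The hypothesis that the whole course is delayed in Tabby could give a negative correlation across probes between the Tabby minus WT difference at P3 and the WT change from P1 to P5. It was -0.17 over the 32121 probes and -0.054 over the 29988 without a genotype call at any stage, but leaving out called probes removes those that a delay would change, so the second value excludes nothing. Of the 2772 probes that fell in WT from P1 to P5, 49.6% were above 0 in Tabby minus WT at P3 (median -0.0029, quartiles -0.1 and 0.09), and of the 3263 that rose 53.1% were below 0. Their quartiles lie on both sides of 0, so a small delay stays open. Probes are not independent replicates here, and the P3 arrays are in neither end of the WT change.

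The largest differences between the Tabby adult replicates included Z00011419-1 (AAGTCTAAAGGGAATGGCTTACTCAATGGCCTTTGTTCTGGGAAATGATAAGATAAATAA), with a log2 Cy3 signal of 14.28 and 7.89 in replicates 1 and 2 against 6.29 and 7.2 in WT adults, and Z00023825-1 (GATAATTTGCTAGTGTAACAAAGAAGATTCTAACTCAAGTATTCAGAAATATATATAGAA), with 11.98 and 6.34 against 6.38 and 6.39. WT E17.5 replicates also differed, in Z00025964-1, at 6.06 and 10.19. Z00064853-1 (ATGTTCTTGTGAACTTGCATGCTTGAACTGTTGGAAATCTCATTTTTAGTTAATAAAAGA), chosen after its values were seen, had a log2 Cy3 signal of 10.03 on WT E17.5 replicate 1, 10.52 to 10.99 on the 6 Tabby arrays of P1, P3 and P5 and 11.2 to 12.27 on the other 13.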
